A study of Mus musculus with 3 samples.

How the data were processed

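RNA was measured after immunoprecipitation (RIP-seq, in which RNA bound to an antibody's target protein is recovered and sequenced) from extracts of C2C12 cells, a mouse myoblast line that forms multinucleated muscle cells when serum is lowered. Per the labels' protocols, the extracts came from day 2 of differentiation in medium with 2% horse serum, and 500 µg of extract went onto the beads. There were 3 libraries, 1 each for an antibody against YB-1, an antibody against HuR and control IgG. Each antibody therefore has no replicate, and no difference between libraries has a replicate check.

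The values came from a single table of the authors' comparison of YB-1 with IgG. It gives the authors' normalized signal per gene for the 3 libraries, which is the read count divided by a size factor per library, and the mean of these as baseMean. The deposited table also gives the authors' moderated log2 fold change of YB-1 over IgG with its standard error, and an unmoderated log2 fold change. It further holds a Wald score, which the authors' columns define as the fold change divided by its standard error, and the deposited p-value and adjusted p-value, all from 1 library per antibody. Per the submitters' processing notes, TopHat2 2.0.10, HTSeq 0.6.1 and DESeq2 were used, with the mouse builds mm10 and GRCm38 (names of the same assembly). Their parameters, and whether reads were counted by strand, are not given in the sources used here. Reads shared between paralogs, overlapping genes or antisense partners therefore cannot be assigned with certainty, which matters most for ribosomal protein and histone genes. The column names of the libraries end in a tag that the labels do not explain.

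The normalized values in each library were whole multiples of the value of 1 read, for 100% of values within 0.01 read, so whole reads were recovered. The libraries held 39112714 reads (YB-1), 24797504 reads (HuR) and 10630155 reads (IgG). In the YB-1 library, 1 read was worth 0.531 normalized counts, against 0.862 for HuR and 2.29 for IgG. The table had 15428 named rows, of which 25 had a calendar date in place of a symbol (gene symbols turned into dates by spreadsheet software) and were left out. These rows held 0.190% of the reads in the YB-1 library, 0.304% in the HuR library and 0.123% in the IgG library, with exact 95% binomial bounds of 0.189 to 0.191, 0.302 to 0.306 and 0.121 to 0.126. No count model was fitted to the recovered reads, because with 1 library per antibody there is no spread between replicates to fit. A paired or replicated analysis was not possible for the same reason.

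The log2 ratio of 2 libraries was taken from the normalized counts without moderation. A library at 0 was set to a floor of 3 reads, and no ratio was taken where both libraries had 3 reads or fewer. A ratio with a floored denominator is a lower bound, and one with a floored numerator is an upper bound. Counts above 0 but below the floor were kept, so their ratio can be more extreme than that of a library at 0. The floor stood at 1.59 normalized counts for YB-1, 2.59 for HuR and 6.88 for IgG. Intervals of a ratio were exact 95% Clopper-Pearson intervals. They cover counting error only, since reads without molecular identifiers are not independent molecules. Ratios against IgG used genes with a baseMean of 10 or more (13043 of 15403 genes). HuR over YB-1 used genes with a mean of 10 or more over the YB-1 and HuR libraries, so that the choice of genes does not depend on the IgG library. This gene set was adopted after a first run on the mean of all 3 libraries had been seen, and that first version is kept as an alternative.

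Before the data were examined, 18 gene lists were fixed. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list is described as standing apart where it lay outside the central 95%. This percentile does not depend on the scaling between libraries. It describes these libraries and says nothing about replicates. The fixed plan did not say which fold change the lists would use: the unmoderated ratio was chosen, and the authors' moderated fold is an added alternative. Fisher tests of called genes inside and outside a list were planned and are not given, since no gene was called. No mitochondrially encoded mRNA was in the table. A second set of marker lists for adult tissues was written after the genes with the largest ratios had been seen, but before the values of the lists were. Some of its members, such as Cd36 and Tcap, were among those genes.

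The genes named in the text follow a rule fixed in advance. Myog, Ybx1 and Elavl1 are always named. The rule then takes the 10 highest and 10 lowest authors' log2 fold changes among genes with a baseMean of 50 or more, by fold alone because no gene passed the threshold, and the 2 members of highest baseMean in each list. Other genes were chosen after their values were seen. These include the extremes of HuR over YB-1 and HuR over IgG among genes with a mean of 1000 or more, and the markers of adult tissues. Some genes that this selection takes are not reported here.

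Gene features were taken from GENCODE M21 on GRCm38, using for each gene the principal protein-coding transcript where there was one. Of the 15403 genes, 14462 matched by symbol, 812 by an older symbol and 129 did not match. The 3' UTR was the transcript after the stop codon, and ATTTA motifs were counted in 3' UTRs of 50 nt or more. Correlations across genes were Spearman rank correlations, with ranks regressed on covariates where these were held fixed, and genes are not independent replicates.

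The ratio and list steps were tested on simulated data for YB-1 over IgG. With 200 of 15403 genes changed and counting noise only, a log2 change of 1 put into 50 genes came back with a median of 1.03, and 2 put into 48 genes came back as 1.99. The exact interval covered the true ratio for 96% of the changed genes. Of 200 random lists of 30 genes drawn from 13022 genes, 4% lay outside the central 95% with no shift, 84% with a log2 shift of 1 and 100% with a shift of 2. Alternatives were other thresholds and expression filters, other adjustments of the p-values, and scaling to the median gene, to ribosomal protein genes or to total reads. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.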

Results

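RNA bound by YB-1 or HuR was sequenced from C2C12 muscle cells at day 2 of differentiation, beside RNA recovered with control IgG. YB-1, encoded by Ybx1, and HuR, encoded by Elavl1, are RNA-binding proteins. The series asks which mRNAs the 2 proteins bind in muscle cells, with Myogenin mRNA (Myog) at its centre. There was 1 library per antibody. The YB-1 library held 39112714 reads, the HuR library 24797504 and the IgG library 10630155. Levels are read counts normalized by the authors' size factors, and intervals cover counting error only.

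Myog encodes a transcription factor that drives myoblasts into differentiation. Its mRNA stood at 45679 normalized counts in the YB-1 library, 229849 in the HuR library and 13754 in the IgG library. Relative to IgG it was 3.32-fold higher in the YB-1 library (95% counting interval 3.24 to 3.41) and 16.7-fold higher in the HuR library (16.3 to 17.1). In the HuR library it was 5.03-fold higher than in the YB-1 library (4.99 to 5.07). The fold of YB-1 over IgG was close to that of other transcripts singled out after their values were seen, with 3.30 for Myh3, 3.21 for Cdkn1a and 3.39 for Gapdh. Of 13022 genes, 651 had a ratio of YB-1 over IgG at or above that of Myog, against 50 of 13024 for HuR over IgG. The IgG library differed in make-up from both others, so a fold over IgG does not by itself measure recovery with an antibody. Myog lies on chromosome 1 from 134289989 to 134292548 on the plus strand of GRCm38, with 3 exons. Its 3' UTR of 753 nt, in the last exon, holds 1 ATTTA motif. In the authors' deposited table the moderated log2 fold change of Myog in YB-1 over IgG was 0.88, with a standard error of 1.09 and an adjusted p of 0.845, so it did not pass the threshold. Its direction turned when that fold was recentred on ribosomal protein genes, to -0.10, whereas the unmoderated ratio recentred in the same way stayed above 0, at 0.56.

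Elavl1 mRNA, which encodes HuR itself, was 8.28-fold higher in the HuR library than in IgG (7.68 to 8.93), with 13792 against 1666 normalized counts. In the YB-1 library it stood at 2847, which is a log2 ratio to IgG of 0.77 that turns to -0.40 when recentred on ribosomal protein genes. Ybx1 mRNA was at similar levels in the 3 libraries, with 44148 in YB-1, 36771 in HuR and 43225 in IgG. Its log2 ratio of YB-1 over IgG was 0.03, or -1.14 after ribosomal recentring. Elavl1 lies on chromosome 8 from 4285382 to 4325413 and has a 3' UTR of 4218 nt with 17 ATTTA motifs. Ybx1 lies on chromosome 4 from 119277981 to 119294604 and has none in 418 nt.

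**Figure D1:**
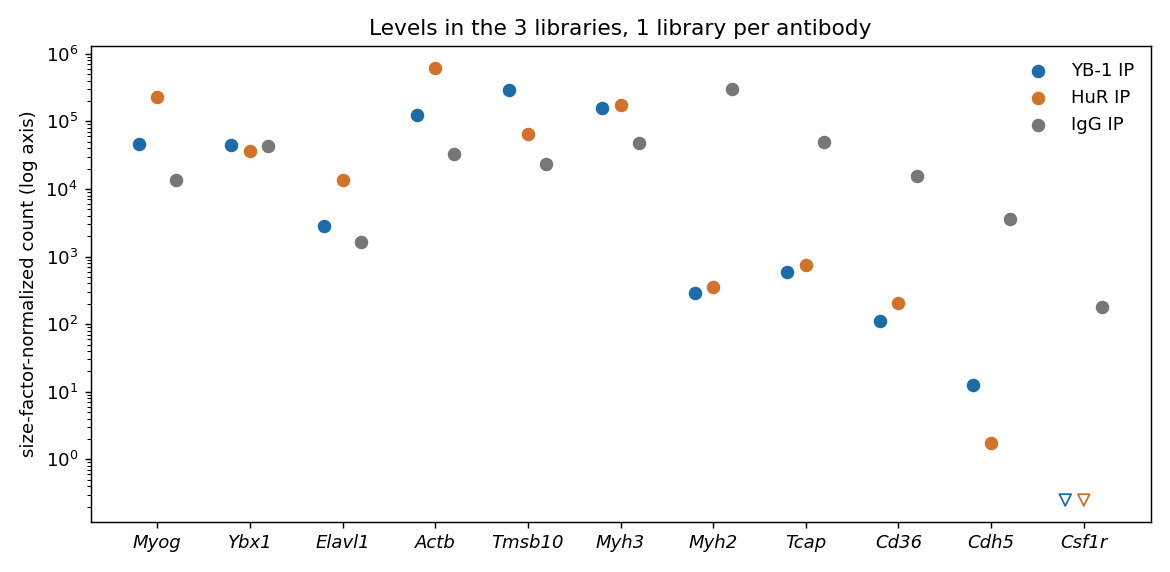
Size-factor-normalized counts (log axis) of 11 genes in the YB-1, HuR and IgG libraries, 1 library per antibody, with open triangles for a library without reads. Myog, Elavl1 and Actb were highest in the HuR library and Tmsb10 in the YB-1 library, while Myh2, Tcap, Cd36, Cdh5 and Csf1r were highest in the IgG library.

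The comparison of YB-1 with IgG addresses which mRNAs are recovered with YB-1. The IgG library stood apart from both others, with 20.8% of its reads in 1516 genes at least 8-fold above both, so the group differences below may reflect the IgG library as well as YB-1. mRNAs for cell cycle and ribosomal proteins were higher in the YB-1 library, and mRNAs of the contractile apparatus and of oxidative phosphorylation were higher in the IgG library. Of 13022 genes with a ratio, 2209 were at least 2-fold higher and 4265 at least 2-fold lower in YB-1 than in IgG. The median log2 ratio of all genes was -0.17, and values are given on the authors' scaling. Recentred on ribosomal protein genes, the counts became 284 and 7757, so the share of higher genes among both moved from 34.1% to 3.53%. Scaled to total reads, it was 44.6%.

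In the authors' deposited table no gene passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.845 (DESeq2, 1 library per antibody). With 1 library per antibody the deposited p-values hold no spread between replicates, so no number of genes expected by chance can be set beside them. Genes are therefore named by the size of their fold alone.

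The 10 genes with the highest authors' moderated fold in YB-1 over IgG were Tmsb10, Igf2, Dynap, Gm14635, Ngfrap1, Mustn1, Tmem184a, Acta2, Hebp2 and Ucp2. The order differs by the unmoderated log2 ratio, which was 3.85 for Tmem184a and 3.67 for Tmsb10. Tmsb10, which encodes the actin-monomer-binding protein thymosin beta 10, stood at 292962 normalized counts in YB-1, 66094 in HuR and 23087 in IgG. That is 12.7-fold higher in YB-1 than in IgG (12.4 to 12.9). The growth factor mRNA Igf2 stood at 17762 in YB-1 and 1448 in IgG, a log2 ratio of 3.62, and Acta2, which encodes smooth muscle actin, had a log2 ratio of 2.76. In the authors' deposited table the moderated log2 fold changes of these 10 genes ran from 2.27 for Tmsb10, with a standard error of 1.08, to 1.90 for Ucp2.

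The 10 genes with the lowest authors' moderated fold were Tcap, Myh7, Neb, Pfn2, Neat1, Nrep, Lmod2, Npr3, Cd36 and Ankrd23. They are not the lowest by the unmoderated log2 ratio, which was -10.00 for Myh2 (moderated -0.87) against -6.37 for Tcap. Several encode parts of the sarcomere, namely Tcap (the titin cap), Myh7 (slow myosin heavy chain), Neb (nebulin) and Lmod2 (leiomodin 2). Myh7 stood at 5333 normalized counts in YB-1 and 5517 in HuR against 356083 in IgG. Neb stood at 2758 and 2876 against 198455, and the nuclear noncoding RNA Neat1 at 549 and 609 against 30985. Cd36, a fatty acid transporter, stood at 111 and 206 against 15395. In the authors' deposited table the moderated log2 fold changes of these genes ran from -2.57 for Tcap, with a standard error of 1.10, to -2.53 for Ankrd23.

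Among 35 cell cycle genes, 27 were at least 2-fold higher in YB-1 than in IgG and 2 at least 2-fold lower, with a median log2 ratio of 1.44 (quartiles 1.02 and 1.80). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, had log2 ratios of 1.44 and 1.02. Of 84 cytosolic ribosomal protein genes, 54 were at least 2-fold higher and 2 lower, with a median of 1.17. Rpsa stood at 89788 normalized counts in YB-1 and 21669 in IgG, and Rps2 at 52623 and 27483. Both lists lay at percentile 100 of their matched random lists, and the cell cycle median stayed above 0, at 0.26, after ribosomal recentring. The 17 translation factor genes with a 5' TOP motif (a start sequence shared with ribosomal protein mRNAs) had a median of 0.57, at percentile 68.0, which turned to -0.60 after ribosomal recentring. Eef1a1 and Tpt1, its most abundant members, had log2 ratios of 1.38 and 1.97.

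Among 45 contractile genes, 25 were at least 2-fold lower in YB-1 than in IgG and 10 at least 2-fold higher, with a median of -1.49 (quartiles -3.44 and 0.45) at percentile 0. Among its members, Myh3 and Myh8, the embryonic and perinatal myosin heavy chains, had log2 ratios of 1.72 and 1.40, against -10.00 for Myh2, an adult fast myosin, and 1.38 for Actn3, a fast-fibre alpha-actinin. These 4 genes were singled out after their values were seen, and no split of the list by isoform was tested. Acta1 and Ttn, the most abundant members, had log2 ratios of -1.86 and -4.66. Of 79 nuclear-encoded oxidative phosphorylation genes, 35 were at least 2-fold lower in YB-1 and 1 higher, with a median of -0.88 at percentile 0, and Atp5b and Atp5a1 had log2 ratios of -0.72 and -1.66. The 31 mRNAs of RNA-binding proteins had a median of -1.19 at percentile 0.03, with 16 at least 2-fold lower and 3 higher. By the mean of -1.10 they lay just inside the range, at percentile 2.56. Pcbp2 was at -1.34. Under each scaling tried these 3 medians stayed below 0.

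Markers of cell types other than muscle, a list fixed in advance, were far higher in the IgG library. Of 16 measured members, 11 were at least 2-fold lower in YB-1, with a median of -5.86 at percentile 0. By the authors' moderated fold, their median of -0.65 lay inside the range, at percentile 7.62. Endothelial Pecam1 had 1228 reads in IgG, 1 in YB-1 and 0 in HuR, and adipocyte Adipoq had 94, 0 and 0. Acta2 and Tubb3, the most abundant members, were instead higher in YB-1, with log2 ratios of 2.76 and 0.69.

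The other lists lay inside the central 95% of their matched lists in YB-1 over IgG. The 22 myogenic regulators had a median of 0.67 at percentile 96.2, with 8 members at least 2-fold higher and 8 lower. Their median was -0.50 after ribosomal recentring, and their mean was below 0, at -0.43. Cdkn1a, which encodes a cell cycle inhibitor induced in differentiation, had a log2 ratio of 1.68. Medians were 0.24 for 22 reported HuR targets, 0.00 for 12 reported YB-1 targets, 0.16 for 16 glycolytic genes and 0.27 for 36 proteasome genes. All of these turned negative after ribosomal recentring, to -0.94, -1.17, -1.01 and -0.90, and the mean of the reported YB-1 targets was -0.23. Medians were below 0 under each scaling for 29 extracellular matrix genes (-0.34), 15 long noncoding RNAs (-1.32), 13 histone genes (-1.53, but -0.37 at a mean of 50 or more and -0.28 with every gene with a fold) and 293 zinc finger genes (-0.65). The 2 small structural RNAs measured, Rpph1 and Rmrp, had log2 ratios of -0.47 and -0.36. The abundant members Fn1 and Timp2 (matrix) had log2 ratios of 1.45 and 1.74, Psmc3 and Psmd2 (proteasome) 0.88 and 0.04, H19 and Malat1 (noncoding) 2.67 and -3.89, H1f0 and Hist1h1c (histone) -0.37 and -1.53, and Zfp106 and Zfp706 (zinc finger) -2.26 and -0.17. Gapdh and Aldoa, glycolytic enzymes, had log2 ratios of 1.76 and -0.71.

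Across genes, log2 YB-1 over IgG had a Spearman rho of 0.247 with mean expression (13022 genes) and of -0.232 with transcript length, expression held fixed. It had rho -0.181 with 3' UTR length and 0.251 with GC content. For HuR over IgG, rho was 0.271 with mean expression, -0.0851 with transcript length, 0.0155 with 3' UTR length and 0.0114 with GC content. For HuR over YB-1, rho with the mean expression of these libraries was 0.0339. The trend with expression was therefore shared by both ratios to IgG and is not particular to YB-1.

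The comparison of HuR with IgG addresses which mRNAs are recovered with HuR. Reported HuR targets and cell cycle mRNAs were higher in the HuR library, and contractile and oxidative phosphorylation mRNAs were higher in the IgG library. As for YB-1, these differences may reflect the IgG library as well as HuR. The cell cycle, contractile and oxidative phosphorylation medians lay on the same side of IgG in the YB-1 library. Between HuR and YB-1, cell cycle genes had a median of -0.15 at percentile 32.8, inside the range. Of 22 reported HuR targets, 14 were at least 2-fold higher and 2 lower, with a median log2 ratio of 1.61 at percentile 100. Actb, which encodes beta actin, stood at 625331 normalized counts in HuR against 32929 in IgG, a log2 ratio of 4.25. The 12 measured reported YB-1 targets had a median of 1.31 at percentile 99.9, and 8 of the 14 in the table sit in other lists as well. Of the 23 reported HuR targets in the table, 8 also sit in other lists, among them the cell cycle genes Ccna2, Ccnb1 and Ccnd1. These directions held under each scaling tried.

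Of 13024 genes with a ratio, 2466 were at least 2-fold higher and 4051 at least 2-fold lower in HuR than in IgG, and the median log2 ratio of all genes was -0.16. The share of higher genes among both was 37.8%, against 21.7% after ribosomal recentring. Cell cycle genes had a median of 1.25, with 23 of 35 at least 2-fold higher, and myogenic regulators 0.80 at percentile 98.9, though their mean of 0.22 lay inside the range, at percentile 87.6. Contractile genes had a median of -2.01 and oxidative phosphorylation genes -1.55, both at percentile 0, with 29 of 45 and 59 of 79 members at least 2-fold lower. Markers of other cell types had a median of -5.08, with the same limit of the expression filter as in YB-1 over IgG. Glycolytic genes had a median of -0.59 at percentile 1.81, and long noncoding RNAs one of 0.83 at percentile 98.9. By the mean both lay inside the range, at -0.64 (percentile 15.3) and -0.94 (percentile 33.0). Ribosomal protein genes, with a median of 0.49 at percentile 82.0, lay inside the range of their matched lists. So did the 5' TOP factors (0.28, or -0.21 after ribosomal recentring and -0.08 by the mean), proteasome genes (-0.17, or 0.03 scaled to total reads), RNA-binding proteins (-0.30), matrix genes (-0.29), histone genes (-1.39, but -0.34 at a mean of 50 or more) and zinc finger genes (-0.41). No p-value for HuR is given, since the authors' deposited table compares YB-1 with IgG.

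Both comparisons used the same IgG library. Among 13003 genes measured in both, 1214 were at least 2-fold higher in both antibodies, out of 2190 for YB-1 and 2445 for HuR. Independent lists of these sizes would share 412. Libraries simulated against a shared control, with a spread across genes taken from HuR over YB-1, shared 941 on average (highest of 100 simulations 1008), out of 2167 and 2165. That spread holds any antibody difference, and the observed spread was larger against IgG (1.69 for YB-1, 1.59 for HuR) than for HuR over YB-1 (0.945). The simulation is therefore no benchmark for libraries without a difference. At least 2-fold lower in both were 3257 genes, where independent lists would share 1329 and the simulation gave 927, but out of only 2141 and 2135 genes against 4265 and 4051 observed, so 927 is no chance value for lists of the observed size. Part of the excess may come from the shared control. Across 13043 genes the Spearman correlation of levels was 0.936 between YB-1 and HuR, 0.783 between YB-1 and IgG and 0.776 between HuR and IgG.

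**Figure D2:**
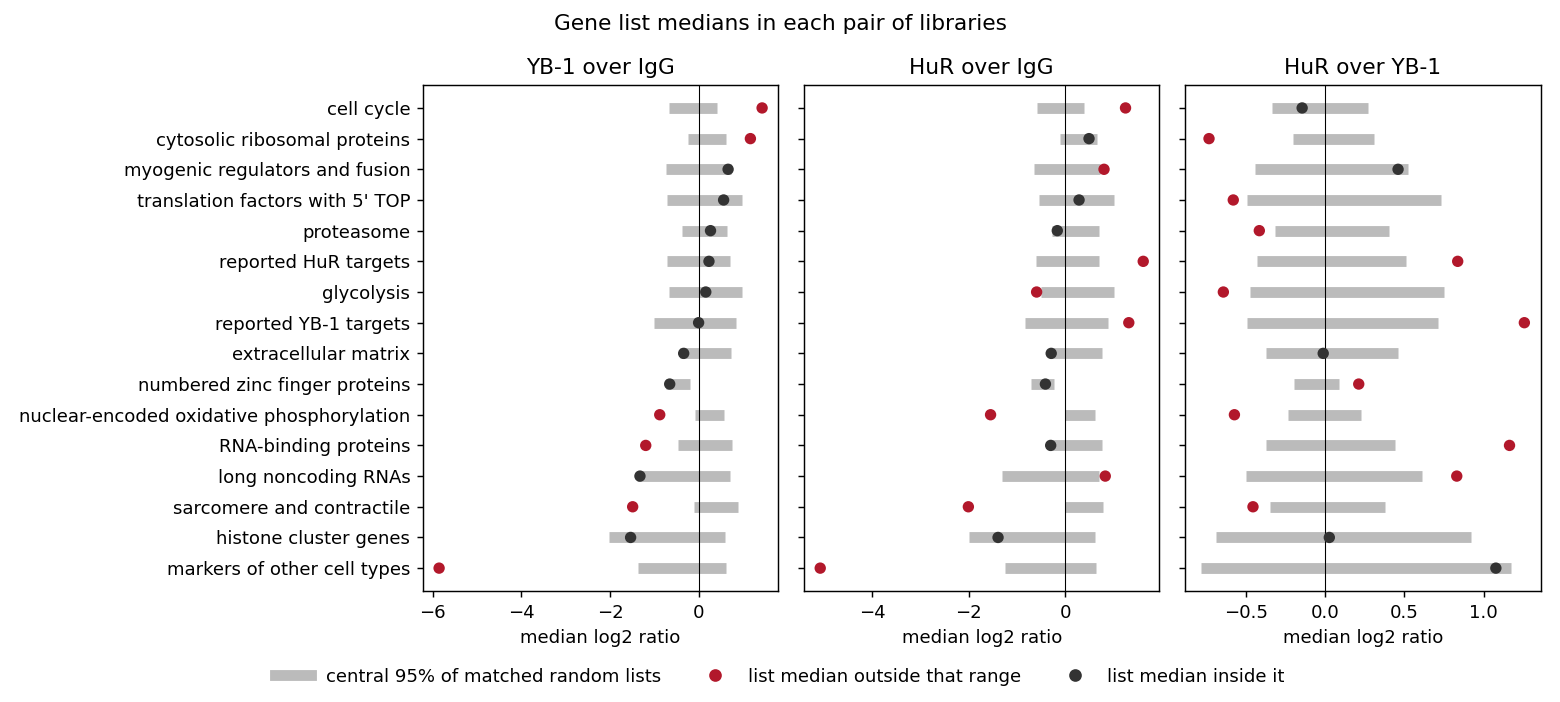
Median log2 ratio of the gene lists other than the small structural RNAs (points) in YB-1 over IgG, HuR over IgG and HuR over YB-1, with grey bars for the central 95% of 10000 random lists matched on expression and red points for medians outside it. Markers of other cell types, which can pass the expression filter through the IgG library alone, lay at -5.86 and -5.08 against IgG. Recentring on ribosomal protein genes turns the YB-1 over IgG medians between 0.00 and 0.67 negative, the 5' TOP factors in HuR over IgG negative and the negative medians in HuR over YB-1 positive, except the ribosomal proteins, which then lie at 0.

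The comparison of HuR with YB-1 takes no reads from the IgG library. Its scaling may still depend on that library, since the authors normalized the 3 libraries together. mRNAs of RNA-binding proteins, reported HuR targets and reported YB-1 targets were higher in the HuR library, and ribosomal protein, oxidative phosphorylation and glycolytic mRNAs were higher in the YB-1 library on the authors' scaling. The first of these lists share members, so their results are not separate. Myog, Hif1a, Vegfa, Ccnd1, Ccna2 and Ccnb1 are in both target lists. Among the reported YB-1 targets, Ybx1 and Pabpc1 are also in the RNA-binding protein list. Of 31 mRNAs of RNA-binding proteins, 18 were at least 2-fold higher in HuR and 1 lower, with a median log2 ratio of 1.16 at percentile 100. Pcbp2, for example, stood at 36026 normalized counts in HuR and 7129 in YB-1. Reported HuR targets had a median of 0.84 at percentile 99.8, with 9 of 22 at least 2-fold higher and 0 lower, and reported YB-1 targets 1.26. With every gene with a fold, the latter had a median of 0.67 inside the range, at percentile 96.8. Long noncoding RNAs (0.83) and zinc finger genes (0.21) also lay above their matched lists. These medians stayed above 0 under each scaling tried.

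Of 82 ribosomal protein genes, 28 were at least 2-fold lower in HuR than in YB-1 and 0 higher, with a median of -0.73 (quartiles -1.14 and -0.44) at percentile 0. Medians also lay below the matched lists for oxidative phosphorylation (-0.57), glycolysis (-0.64), the 5' TOP factors (-0.58), contractile genes (-0.46) and the proteasome (-0.42). Relative to ribosomal protein genes these 5 medians turned positive, to 0.16, 0.09, 0.15, 0.28 and 0.32. Myogenic regulators had a median of 0.46 at percentile 96.2, inside the range. Also inside it were cell cycle genes (-0.15, or 0.59 relative to ribosomal protein genes), matrix genes (-0.01, or 0.72), histone genes (0.03, or -0.01 scaled to total reads, -0.17 by the mean and -1.35 with every gene with a fold, at percentile 1.62) and 7 markers of other cell types (1.08).

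Of 11868 genes with a ratio, 2289 were at least 2-fold higher in HuR and 1263 at least 2-fold lower, with a median of -0.06. The share of higher genes among both was 64.4%, against 90.7% after ribosomal recentring. The genes named next were chosen after their values were seen, from the 10 highest and 10 lowest among genes with a mean of 1000 or more. Highest were Ccnc, Naa30, Pmaip1, Sox4, Srsf9, Snrpf, Tmx3, Ube3a, Klf5 and Tcf4, with log2 ratios from 4.37 for Ccnc to 3.35 for Tcf4. Pmaip1, which encodes the apoptosis protein Noxa, stood at 8448 normalized counts in HuR and 653 in YB-1. Among the lowest were Clec2d, Atp5e, Tmsb10, Tmem147, Dnajb1, Rps12, Ubb and Rplp2. Of the genes named here, Rps12 and Rplp2 are members of the ribosomal protein list. Tmsb10 had a log2 ratio of -2.15.

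Genes with more ATTTA motifs, the core of AU-rich elements, were higher in the HuR library relative to YB-1. The median log2 ratio was -0.37 for 3543 genes without a motif in the 3' UTR and 0.34 for 2754 genes with 2 to under 4 per kb, and 0.15 for 1233 genes with 4 or more. Across 11291 genes, the Spearman correlation of log2 HuR over YB-1 was 0.285 with ATTTA density and 0.356 with the AU content of the 3' UTR. With expression held fixed, it was 0.309 with 3' UTR length (11435 genes) and 0.248 with transcript length (11798 genes). With the length and AU content of the 3' UTR held fixed, the correlation with ATTTA density fell to 0.0581. That with transcript GC content was -0.370 (11798 genes, expression held fixed), or -0.420 among 10217 genes with a mean of 50 or more. Against IgG, the correlation with ATTTA density was 0.0088 for HuR and -0.196 for YB-1. With the length and AU content of the 3' UTR held fixed, these were 0.0139 and -0.0181.

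**Figure D3:**
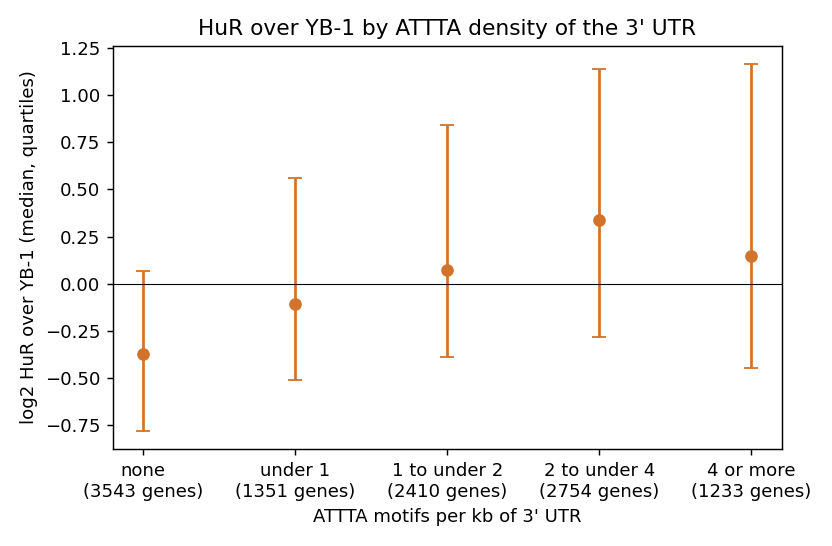
Log2 HuR over YB-1 (points, median over genes, and bars, quartiles) by the number of ATTTA motifs per kb of 3' UTR. The median was -0.37 without a motif and 0.34 in the class of 2 to under 4 per kb.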

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

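For 3 lists the median ratio to IgG had opposite signs in the YB-1 and HuR libraries, also relative to the median gene. The difference was not tested, since each antibody had 1 library. The comparison of signs was chosen after the ratios had been seen. Glycolytic genes had a median log2 ratio of 0.16 in YB-1 over IgG and -0.59 in HuR over IgG. Gapdh stood at 287728 normalized counts in YB-1, 89770 in HuR and 84876 in IgG. Long noncoding RNAs had medians of -1.32 and 0.83, and their mean in HuR over IgG was below 0, at -0.94. Proteasome genes had medians of 0.27 and -0.17, of which the HuR value became 0.03 when scaled to total reads. Recentred on ribosomal protein genes, the opposite signs remained for the long noncoding RNAs alone: glycolytic genes had -1.01 and -1.09, and proteasome genes -0.90 and -0.66.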

How the results depend on the processing

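The counts by 2-fold ratio, the scalings applied to them, the lists in the HuR comparisons, the authors' moderated fold for the lists and the choice of genes by the mean of 3 libraries were added after the data were seen. No gene in the authors' deposited table passed under any planned threshold, filter, adjustment or recentring. Recentring on ribosomal protein genes reversed the moderated log2 fold change of Myog in the authors' deposited table to -0.10. The same recentring gave 284 genes at least 2-fold higher and 7757 lower in YB-1 than IgG, 1473 higher in HuR than IgG, and 4383 higher and 451 lower in HuR than YB-1. Its construction, a subtraction of the ribosomal median, accounts for these shifts. A mean of 50 or more left 804 genes at least 2-fold lower in HuR than YB-1, because fewer genes enter. The other 20 such counts stayed within 1.5 times. In YB-1 over IgG, 65 list results under alternatives kept their side of the central 95%. The exceptions were the RNA-binding proteins by the mean (-1.10, percentile 2.56) and markers of other cell types by the moderated fold (-0.65, percentile 7.62), the cause of which was not tested. In the HuR comparisons, the long noncoding RNAs over IgG had a mean of -0.94 where the median was positive, and histone genes over YB-1 had a median of -1.35 when every gene with a fold entered; the cause was not tested. The histone median moved to -0.37 (mean of 50 or more), -0.28 (every gene with a fold) and -0.55 (moderated fold) in YB-1 over IgG, and to -0.34 (mean of 50 or more) in HuR over IgG. By the mean, myogenic regulators (0.22, percentile 87.6) and glycolytic genes (-0.64, percentile 15.3) in HuR over IgG moved inside the range, as did reported YB-1 targets in HuR over YB-1 with every gene with a fold (0.67, percentile 96.8). Means with the opposite sign to a median inside the range were -0.43 for myogenic regulators and -0.23 for reported YB-1 targets in YB-1 over IgG, -0.08 for 5' TOP factors in HuR over IgG and -0.17 for histone genes in HuR over YB-1. Myogenic regulators in HuR over YB-1, inside the range at percentile 96.2, lay outside it at 98.1 when genes were chosen by the mean of 3 libraries, as in the first run. Markers of other cell types did so too, at 99.0, and at 97.6 with every gene with a fold. No paired analysis was possible because each antibody has 1 library, and for that reason edgeR, DESeq2 and leaving out replicates were not run. The spread of log2 HuR over YB-1 across genes was 1.90 at a mean of 10 to 50, 0.989 at 50 to 200, 0.779 at 200 to 1000, and 0.875 and 1.19 in the 2 classes above that. How far depth sets it was not tested.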

Other observations

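The tests of marker lists were made on lists written after the largest ratios had been seen. Chosen after results were seen were also the test of an unrelated sample, the tests of GC bias, the length-matched test of contractile genes, and both tests of depth by counting intervals. The length-matched test was added because the first length test had left the question open. The tests of depth were changed more than once: thinning reads could not have come out the other way, and a share of genes against a fixed limit had no value for other genes beside it, so the share is now set against lists matched on expression. A first test of GC bias held only coding GC fixed, which leaves the GC of 3' UTRs free, and was replaced. The correlations with HuR over YB-1 were recomputed on the genes chosen by the YB-1 and HuR libraries after a first run. Each spread given below with a value comes from the genes of these single libraries. Genes are not independent replicates, so it says nothing about how far a repeat of the experiment would differ.

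The IgG library held many transcripts that were almost absent from both other libraries. At least 8-fold above both were 1516 genes, which held 20.8% of IgG reads (exact 95% bounds 20.8 to 20.9). Of 2264 genes without reads in YB-1 and HuR, 792 had more than 10 reads in IgG, although this was the shallowest library. Of 16 adult muscle markers, 14 were at least 4-fold higher in IgG than in the mean of the others. In the YB-1 library 12 of the 16 reached 100 normalized counts, and 12 are in a list fixed in advance. Myh2 stood at 301284 normalized counts in IgG, 293 in YB-1 and 353 in HuR. All 14 endothelial markers, all 11 measured immune markers and 8 of 9 adipose markers were at least 4-fold higher in IgG, among them Fabp4 (5386 against 1.06 and 10.3). Of the 43 blood, endothelial, immune and adipose markers in the table, 4 reached 100 normalized counts in YB-1 and 9 are in a list fixed in advance. Red blood cell markers were sparse, with 96 reads in IgG. The 4 Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 1350 reads in IgG, 1 in YB-1 and 2 in HuR. Of 9 nerve and glia markers, 5 were at least 4-fold higher in IgG. Among the negative controls, the liver list had 1 gene with enough reads, Cyp2e1, and the testis and kidney lists had 0. Cyp2e1 had 142 reads in IgG, 0 in YB-1 and 1 in HuR, so the only measurable control gene behaved like the other markers. The other liver markers, Alb, Apoa1 and Serpina1a, did not pass the expression filter, so their low levels did not enter. The liver control thus rests on 1 gene, which passed the filter through the IgG library alone, and decides nothing. Without a usable control, the markers do not by themselves single out a tissue. The expression filter can be met by the IgG library alone, and 21 of the 36 blood, endothelial, immune and adipose markers that passed it had no reads in either other library. Checks added for this reason gave a median log2 ratio of 5.97 for all 43 markers without the filter, and 5.18 for the 5 with a mean of 10 or more over YB-1 and HuR. Lists of 36 genes matched on expression had medians from -0.33 to 1.24 in the central 95%. The make-up of the IgG library enters every ratio to IgG, and whether it also sets the cell cycle, ribosomal protein and oxidative phosphorylation medians against IgG was not tested.

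Mature muscle mRNAs were higher in the IgG library. The exact 95% counting interval of YB-1 over IgG lay wholly below the median gene for 64.4% of 45 contractile genes (spread 7.14). All genes gave 43.3%, and lists matched on expression 20.0% to 46.7% in the central 95%. Counting error alone therefore does not place most of these genes low. The share largely restates the list's percentile 0 among such lists, so it decides nothing further on the lower depth of the IgG library. Transcript length is argued against, since contractile genes lay at percentile 0 of lists matched on length and expression. The first test of length, on the 29 short members, gave a median of -0.55 with a spread of 0.53 and decided nothing. A complete replacement by a sample without Myog, Myh3, H19 and Igf2 mRNA is argued against, since their IgG level was a median 0.229 of that in YB-1 (0.0815 to 0.303). Replacement by another sample that holds these mRNAs was not tested. RNA from other cells or adult tissue in the IgG library is a candidate explanation, since 36 markers of blood, endothelial, immune and adipose cells had a median log2 ratio of 6.39 (spread 0.33). The 4 Y-linked genes, added after the data were seen and covered by no prediction, go the same way. They had 1350 reads in IgG, against 1 in YB-1 and 2 in HuR, both deeper libraries. The source of such RNA is open. The 1 measured liver control gene could pass the expression filter through the IgG library alone, so it decides nothing. At what step such RNA could have entered, and its binding to IgG beads, were not tested.

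AU-rich mRNAs were higher in the HuR library than in the YB-1 library. Length of the 3' UTR alone is argued against by a partial correlation with ATTTA density of 0.222 (spread 0.0094) with length and expression held fixed. GC bias acting along the whole transcript is argued against, since the correlation with coding GC of -0.227 became 0.0320 (spread 0.0093) with the AU content and length of the 3' UTR and expression held fixed. ATTTA motifs, general AU content of the 3' UTR and a GC bias acting on the 3' UTR alone cannot be told apart, because the correlation with ATTTA density was 0.0581 (spread 0.0097) with AU content fixed, and 0.0493 on the genes of the first run. Against IgG, the correlation with ATTTA density was 0.0088 for HuR and -0.196 for YB-1. With the length and AU content of the 3' UTR held fixed, these were 0.0139 and -0.0181. Whether HuR recovers more AU-rich mRNAs or YB-1 fewer stays open, since the IgG library stands apart.

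Ribosomal protein mRNAs were higher in the YB-1 library than in the HuR library. Transcript length is argued against as the whole cause: their median of -0.73 lay at percentile 0 of lists matched on length and expression, which had a median of -0.39. The exact 95% counting interval of HuR over YB-1 lay wholly below the median gene for 92.7% of 82 genes (spread 2.88). All genes gave 40.8%, and lists matched on expression 34.1% to 56.1% in the central 95%. Counting error alone therefore does not place most of these genes low. The list already lay at percentile 0 of lists matched on expression, so the share decides nothing further on the lower depth of the HuR library. A difference in what the antibodies recover remains open, and it cannot be separated from a difference between single libraries.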
